A study of Saccharomyces cerevisiae and Saccharomyces paradoxus and Saccharomyces mikatae with 12 samples.

How the data were processed

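Samples were meiotic cultures of 5 strains of 4 Saccharomyces species, 2 cultures per strain, which the labels call biological replicates. Cultures were taken after 4 hours in sporulation medium (YPS128, S. paradoxus and S. mikatae), 6 hours (UWOPS) or 9 hours (S. kudriavzevii). S. mikatae was grown and sporulated in other media than the rest. Per the labels' protocols, cells were fixed with formaldehyde, their chromatin was digested with a series of MNase amounts, DNA of mononucleosome size was cut from agarose gels and libraries were sequenced on Illumina machines. The libraries used here had been digested with 20 units (YPS128, S. paradoxus and S. kudriavzevii), 10 units (UWOPS and S. mikatae culture B) or 5 units (S. mikatae culture A), plus the 40 unit technical replicates of YPS128 culture B and S. paradoxus culture A.

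The values deposited by the authors are sequencing coverage, a whole number at every base of the 16 nuclear chromosomes, not scaled between libraries. Per the submitters' processing notes, BWA, Picard and bedtools were used and the build was sacCer2; versions, read filters, the handling of reads with several matches and the genomes of the other species are not given in the sources used here. The S. cerevisiae tables have as many rows per chromosome as S288C R64, but coverage stopped 363 bases short of the end of chromosome XI, and start codons of the R64 gene table on its right side lay at an offset of -361 bp from those in the profile (bootstrap SD 4.06 bp). The tables were therefore read as sacCer2 coordinates padded at the right. The gene table (RefSeq, assembly R64) was used only for names and gene neighbours in the text, and genes were measured only on chromosomes VIII and XIV, where coverage ended 1 base from the table's end and start codons lay within 3 bp of the profile's on each side (bootstrap SD 2.54 to 6.17 bp). A length change that cancels within a chromosome was not excluded, so the upstream window was also moved by 15 bp either way, which moved 23 (left) and 27 (right) of the 58 strain values of named group members by more than their SD. No coordinates were converted.

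Mean coverage was 130, 128 and 161 for YPS128 A, B at 20 units and B at 40 units, 160 and 131 for UWOPS A and B, 67.1, 58.3 and 73.5 for S. paradoxus A at 20 units, A at 40 units and B, 69.5 and 64.7 for S. mikatae, and 58.3 and 67.0 for S. kudriavzevii. Bases with no coverage made up 5.03% to 5.87% of the S. cerevisiae tables, 7.57% to 8.28% in S. paradoxus, 1.08% and 2.06% in S. mikatae and 1.06% and 0.939% in S. kudriavzevii. Coverage overlaps from base to base and is not a count of fragments, so no counting intervals were computed from it.

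Occupancy was coverage divided by the library mean, leaving positions over 5 times the median out of that mean. The scaling sets every library to the same average, so a change of nucleosome number in the whole genome is not measurable. NDRs were runs of 80 to 1000 bp under 0.4, and regions with more than 20% of bases uncovered in every library of a strain were left out. For the S. cerevisiae strains, NDRs called on the strain means were merged, and mean occupancy was compared as log2(occupancy + 0.1) with limma 3.58.1 (R 4.3.3; lmFit, eBayes with trend) and Benjamini-Hochberg adjustment at 0.05. Log2 differences are on that scale and understate changes near 0. Genes were tested alike, by the mean from 250 to 50 bp upstream of the start codon. The 13 gene groups were tested with camera (preset correlation 0.01, and estimated) where at least 3 genes were measured; their medians were set against 10000 random lists. Strain measures (spacing, NDR number, width and contrast) were compared by exact permutation of the F statistic. Values over 3 were set to 3 for spacing and contrast. Peak distances were taken after smoothing over 75 bp, between peaks at least 120 bp apart, and distances over 250 bp were left out. Gaps of 150 to 1000 bp between genes were sorted by the direction of their genes. Other tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

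For the match between genomes, 3 kb windows in 10 bp bins were slid over each target by normalized cross-correlation. A window was placed when its best position was within 3 kb of the distance expected from a neighbouring window. Forward and reverse matches were searched separately and the share placed counts forward matches, with shuffled positions as chance. The plan had named the reversed profile as chance, which is no chance level once both orientations are searched.

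The rule for named items, fixed before the data were examined, took genes past the threshold (at most 12 per direction), every member of gene groups of at most 12 measured genes, the 4 largest differences of larger groups, the 10 NDRs with the largest differences per direction and the 8 longest segments without coverage per strain. The other NDRs on chromosomes VIII and XIV were named because their genes are known. Gene groups, tests and most alternatives were also fixed before the data were examined: other pseudocounts, quantile normalization, 1 MNase amount alone, culture letter as a block, each culture left out, other NDR definitions, windows and filters.

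The limma comparisons, spacing, NDR calling, the permutation test and window placement were tested on simulated data, and the other procedures were not. In the NDR comparison (7316 regions, 200 changed) limma recovered 24.0% of changes of log2 1 and 91.0% of log2 2, with 6 unchanged regions among 121 called. In the gene comparison (650 genes, 100 changed) it recovered 84.0% and 100%, with 3 unchanged among 95 called. The noise was drawn independently for each region or gene and culture, so shifts of a whole culture were not simulated. In simulated arrays with repeats of 155, 165 and 175 bp, peak distances were 156, 165 and 175 bp and the autocorrelation lag was 130, 160 and 177 bp. NDRs of 180 bp were found in 99.9% of cases, with median widths of 161 to 164 bp. Of 60 simulated sets with no difference between strains 5 had an exact permutation p under 0.05, and all of 20 sets with one did. With noise of 0.3 and 0.6, 99.4% and 67.8% of forward windows were placed. Of the windows in an inverted block, 100% and 76.9% were placed in reverse. Outside that block 6 and 18 windows were wrongly placed in reverse.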

Results

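Nucleosome positions were mapped in meiotic cultures of 4 budding yeast species by digesting formaldehyde-crosslinked chromatin with micrococcal nuclease (MNase), which cuts linker DNA, and sequencing the mononucleosome-sized DNA. The series held 12 libraries from 10 cultures, 2 per strain. The strains were the wild-derived S. cerevisiae strains YPS128 and UWOPS (named here as in the sample titles, with the full strain name in the plots), S. paradoxus YPS138, S. mikatae IFO1815 and S. kudriavzevii ZP591. Culture B of YPS128 and culture A of S. paradoxus were each digested with both 20 and 40 units of MNase, and these pairs of libraries were averaged into 1 culture. Mean coverage per base was 128 to 161 in the 5 S. cerevisiae libraries and 58.3 to 73.5 in the 7 libraries of the other species. Occupancy is given as coverage divided by the library mean, so that 1 is the average of the nuclear genome. A nucleosome-depleted region (NDR) is a run of 80 to 1000 bp with occupancy under 0.4. Positions in S. cerevisiae are on sacCer2. Genes were analysed on chromosomes VIII and XIV only, where 693 protein-coding genes were placed and 650 tested.

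The first comparison asked where nucleosomes lie around genes in the S. cerevisiae strains. In all 4 cultures occupancy fell to a minimum of 0.347 to 0.414 at 133 to 140 bp upstream of the start codon, the usual place of the promoter. Peaks followed inside the gene, at 42 to 59, 162 to 169, 340 to 342 and 499 to 501 bp downstream, the first pair closer together than the later ones. Gene bodies had a mean occupancy of 1.27 ± 0.0581 (SD, n = 2 cultures) in YPS128 and 1.29 ± 0.0118 (SD, n = 2) in UWOPS. The window from 250 to 50 bp upstream of start codons had 0.531 ± 0.0486 and 0.558 ± 0.00361 (SD, n = 2 each). The 25 tRNA genes, transcribed by RNA polymerase III, were at 0.306 ± 0.0525 in YPS128 and 0.193 ± 0.0367 in UWOPS (SD, n = 2 each). The 6 snoRNA genes were at 0.735 ± 0.267 and 0.785 ± 0.136 (SD, n = 2 each). These strain differences were not tested, and the classes of features were chosen after the data had been examined.

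**Figure D1:**
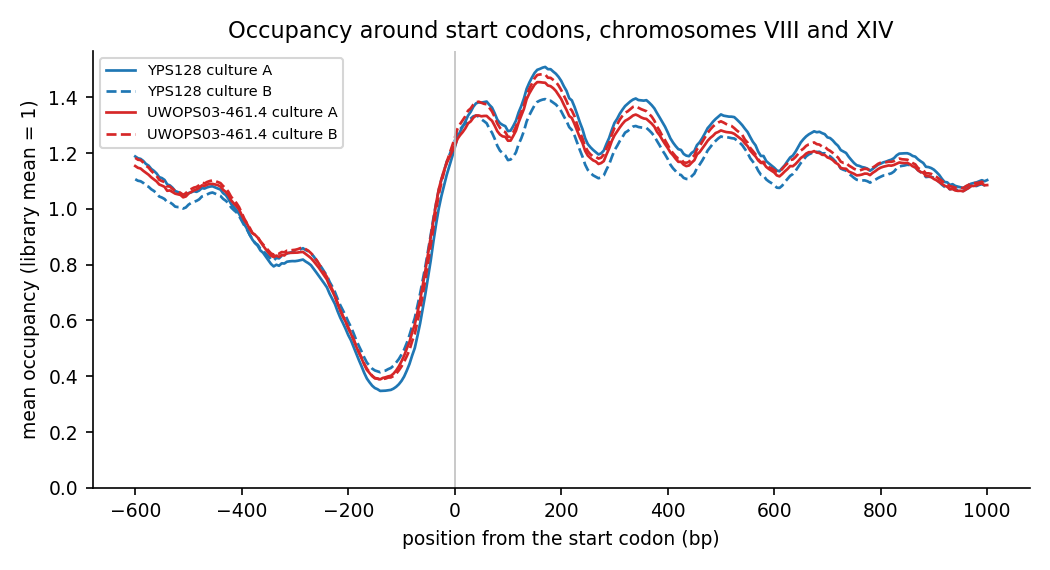
Mean occupancy (library mean = 1, y axis) against the position from the start codon in bp (x axis) for 650 genes of chromosomes VIII and XIV, 1 line per culture of YPS128 and UWOPS. All 4 lines reach their minimum, 0.347 to 0.414, at 133 to 140 bp upstream and show a series of peaks downstream.

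Of the 6 gene groups with at least 3 measured genes, ribosomal protein genes had the lowest upstream occupancy. The 15 measured members had a median upstream occupancy of 0.191, against 0.458 for all 650 genes. A list of the same size drawn at random was that low in 0.02% of 10000 draws. The group median was 0.140 and 0.251 in YPS128 cultures A and B, and 0.164 and 0.177 in UWOPS. RPL14B, which encodes a large-subunit protein, had 0.0633 ± 0.0110 in YPS128 and 0.0560 ± 0.00152 in UWOPS (SD, n = 2 each). The group was gathered by name and included RPP1, a subunit of ribonuclease P, at 0.455 ± 0.0716 and 0.368 ± 0.0253 (SD, n = 2 each). RPS4B stood apart at 1.47 ± 0.0121 and 1.29 ± 0.136 (SD, n = 2 each); these 3 members were chosen after their values were seen. The 7 ribosome biogenesis genes had a median of 0.297, at percentile 13.0 of random lists. In YPS128 the values were 0.204 for NOP2, an rRNA methyltransferase, 0.301 for GAR1, a protein of snoRNA particles, 0.306 for UTP9, 0.102 for the helicase gene DBP2, 0.322 for DBP8, 0.415 for IMP3 and 0.112 for IMP4. In UWOPS the same 7 genes had 0.224, 0.292, 0.30, 0.110, 0.390, 0.433 and 0.112.

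Genes of meiotic recombination and sporulation were looked at one by one. In YPS128, SPO11, whose product makes meiotic double-strand breaks, had an upstream occupancy of 0.142 ± 0.102, its partner REC104 0.507 ± 0.200, and RAD50, of the break-processing complex, 1.07 ± 0.139 (SD, n = 2 each). The corresponding UWOPS values were 0.0975 ± 0.0371, 0.517 ± 0.0382 and 0.968 ± 0.0605 (SD, n = 2 each). SAE3, which helps load the recombinase Dmc1, was among the 8 lowest genes at 0.0700 ± 0.0328 and 0.0637 ± 0.0140 (SD, n = 2 each). SPO16, a crossover factor, had 0.211 and 0.175, SPO13, which acts in the first meiotic division, 0.190 and 0.158, and RIM4, an RNA-binding regulator of meiosis, 0.158 and 0.245 in YPS128 and UWOPS. The 3 middle sporulation genes differed widely. NDT80, the transcription factor of the middle genes, had 0.700 ± 0.144 and 0.885 ± 0.172, SSP1, needed for the prospore membrane, 0.0762 ± 0.0410 and 0.0750 ± 0.0278, and SPS100, of the spore wall, 0.640 ± 0.292 and 0.851 ± 0.0860 (SD, n = 2 each). The medians of the double-strand break and middle sporulation groups lay at percentiles 59.6 and 84.1 of random lists.

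Among metabolic genes, the acetate genes MLS1 and CIT1 had 0.366 ± 0.181 and 0.25 ± 0.166 in YPS128 and 0.370 ± 0.0537 and 0.346 ± 0.0137 in UWOPS (SD, n = 2 each). The glycolytic gene ENO2 had 0.254 ± 0.167 and 0.253 ± 0.0219 (SD, n = 2 each). The stress genes SOD2 and YGP1 had 0.480 and 0.660 in YPS128, and 0.525 and 0.723 in UWOPS. HHT2 and HHF2, a divergent pair encoding histones H3 and H4, had 0.552 and 0.288 in YPS128 and 0.555 and 0.192 in UWOPS. The transporter and flocculation genes were at a median of 0.702, percentile 87.0. The hexose transporter genes HXT1, HXT4 and HXT5 had 0.982, 0.373 and 0.402 in YPS128, the ammonium permease gene MEP2 1.06 and the flocculin gene FLO5 0.673. In UWOPS the same 5 genes had 1.00, 0.424, 0.462, 0.852 and 0.731.

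Upstream occupancy was then compared between the S. cerevisiae strains, gene by gene. Of the 650 genes, 3 differed, all with more occupancy in UWOPS (limma, Benjamini-Hochberg adjusted p under 0.05). An unadjusted limma p under 0.05 was reached by 30 genes, no more than expected at that threshold without any difference. The balance of directions depended on the setting: 4 genes were higher and 4 lower in UWOPS with quantile normalization, 11 and 21 without YPS128 culture A, 122 and 17 without YPS128 culture B, and 4 and 6 without the coverage filter. SNO2, a subtelomeric gene of the vitamin B6 pathway, rose from 0.594 ± 0.0972 in YPS128 to 1.54 ± 0.0475 in UWOPS (SD, n = 2 each). Its log2 difference was 1.25 ± 0.13 (SE; limma adjusted p = 0.0379), with both UWOPS cultures above both YPS128 cultures. YHL009W-A and YHL009W-B, overlapping genes of a Ty4 retrotransposon, share 1 upstream window. That window rose from 0.0356 ± 0.0251 to 7.45 ± 0.0297 (SD, n = 2 each), a log2 difference of 5.81 ± 0.15 (SE; limma adjusted p = 3.54e-05). With the lowest 50 bp upstream of the start codon in place of that window, YHL009W-A had a log2 difference of 1.91 and did not pass (limma adjusted p = 0.110, the highest of a range from 2.04e-257 over the settings tried). The YHL009W-A and YHL009W-B genes themselves had no coverage over 72.0% and 86.0% of their bases in YPS128 and 100% in UWOPS. Their level is uncertain because reads of repeated elements can be shared between copies or lost. SNO2 belongs to a family of near-identical subtelomeric genes, and the same caution applies.

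No fixed gene group differed between these strains as a set. The lowest adjusted p of camera was 0.518 with the preset correlation and 0.940 with an estimated correlation. For the subtelomeric and the transporter and flocculation groups the median log2 difference was above 0 (0.04 and 0.13) while camera's direction was down, neither past the threshold. Of the 21 subtelomeric genes, 1 passed the test over all genes, and 7 passed when adjusted over the list alone. The 4 largest differences in that list were YNR077C at 0.928 ± 0.303 in YPS128 and 3.61 ± 0.546 in UWOPS, YNR075C-A at 0.495 ± 0.185 and 0.114 ± 0.00435, PAU6, of the seripauperin family, at 0.437 ± 0.169 and 0.106 ± 0.00555, and SNO2 (SD, n = 2 each). Some of these genes lacked coverage themselves: PAU6 over 81.8% of its bases in YPS128 and 100% in UWOPS, SNO2 over 33.5% and 30.8%, and YNR077C over 1.96% and 29.0%. In the other 12 groups no gene passed, over all genes or when adjusted over the list alone. Among ribosomal protein genes the largest log2 differences were -0.48 for RPL42A, -0.29 for RPS7B, -0.28 for RPS19B and 0.28 for RPL27A, none past the threshold. The count of 3 genes depended on the YPS128 libraries: without culture A 32 genes passed and without culture B 139. SNO2 did not pass with either UWOPS culture left out (limma adjusted p = 0.312 without A and 0.594 without B), with a window from 200 to 1 bp (0.285) or with the window moved 15 bp to the left (0.0662), out of a range of 5.00e-18 to 0.594 over the settings tried.

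NDRs were compared between the same strains over the whole nuclear genome. Of 7316 regions, 62 differed in occupancy, 48 lower and 14 higher in UWOPS (limma, Benjamini-Hochberg adjusted p under 0.05). The regions that differed lay mainly near chromosome ends. Within 50 kb of an end lay 46 of the 62 (74.2%), against 856 of the 7254 other regions (11.8%; Fisher's exact test, odds ratio 21.5, p = 2.10e-29), a comparison chosen after the data had been examined. Among regions with a mean under 0.4 in 1 strain only, 40 of the 56 differing and 127 of the 448 other regions lay there (71.4% and 28.3%; Fisher's exact test, odds ratio 6.32, p = 5.51e-10). Both directions showed it, with 36 of the 48 lower and 10 of the 14 higher regions near an end.

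On chromosomes VIII and XIV, 8 of the 11 differing regions lay inside genes. As gene bodies are mostly occupied, a region inside a gene can enter the tested set through the strain difference itself, and the share was therefore compared among regions with a mean under 0.4 in 1 strain only. Of these, 8 of the 10 differing and 25 of the 52 other regions lay inside genes (80% and 48.1%; Fisher's exact test, odds ratio 4.32, p = 0.0880, chosen after the data had been examined), which did not pass 0.05. In UWOPS the interior of FLO5, a flocculin gene (VIII 526578 to 526704), was depleted to 0.164 ± 0.0204 from 2.21 ± 0.725 in YPS128 (SD, n = 2 each; log2 difference -3.10 ± 0.22, SE; limma adjusted p = 5.49e-05). DOG1, which encodes a 2-deoxyglucose-6-phosphate phosphatase, was depleted to 0.287 ± 0.0431 from 2.00 ± 0.226 (VIII 194152 to 194266), and its tandem neighbour DOG2 to 0.0860 ± 0.000390 from 0.873 ± 0.160 (VIII 193028 to 193177; SD, n = 2 each). NOG2, a GTPase gene of large-subunit ribosome assembly (XIV 722366 to 722492), had 0.193 ± 0.0117 against 1.28 ± 0.216 (SD, n = 2 each). YNL034W (XIV 571010 to 571091) had 0.200 against 1.56, and YNL018C (XIV 601433 to 601561) 0.0641 against 0.644. The opposite held for the hexose transporter gene HXT17 (XIV 774010 to 774195), which was depleted in YPS128 at 0.0390 ± 0.00690 and occupied in UWOPS at 1.61 ± 0.119 (SD, n = 2 each; log2 difference 3.62 ± 0.40, SE; limma adjusted p = 0.00129). COS8, of the COS family of subtelomeric genes (VIII 6638 to 6825), rose from 0.203 ± 0.0394 to 2.55 ± 0.242 (SD, n = 2 each). Between genes, the regions with lower occupancy in UWOPS were those between MET2 and BOR1 (XIV 119113 to 119208), between COS10 and YNR075C-A (XIV 781106 to 781288) and beyond YNR077C (XIV 783910 to 784041). FLO5, HXT17, COS8, DOG1, DOG2, YNL034W and YNL018C have close copies in the genome, and reads can be shared between copies or lost. FLO5 had no coverage over 13.1% of its bases in YPS128 and 14.7% in UWOPS, YNL034W had none over 8.54% in UWOPS, and part of COS8 also had none in UWOPS. With UWOPS culture A or B left out, DOG2, YNL018C and the 3 regions between or beyond genes no longer passed, nor did COS8 without culture B.

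Over all chromosomes the largest fall was on XII 1060632 to 1060844, from 7.73 ± 1.56 in YPS128 to 0.215 ± 0.0243 in UWOPS (SD, n = 2 each; log2 difference -4.62 ± 0.10, SE; limma adjusted p = 1.82e-09). Apart from FLO5 at -3.10, the next were -3.80 on VII 1082425 to 1082897, -3.43 on XI 24621 to 24779, -3.27 on IV 1523632 to 1524411, -3.14 on X 714896 to 715044, -3.05 on IX 391143 to 391322, -3.04 on XIII 42171 to 42254, -2.97 on III 364 to 478 and -2.89 on I 25026 to 25196. After HXT17 and COS8, the largest rises in log2 occupancy were 2.65 on II 417264 to 417478, 2.43 on XII 814950 to 815043, 2.23 on IV 1523147 to 1523233, 2.16 on III 5386 to 5512, 2.13 on II 86619 to 86700, 1.79 on IX 391328 to 391409, 1.78 on XVI 253123 to 253234 and 1.78 on XII 11548 to 11671. Of these 8 rises, that on II 417264 to 417478 alone passed with either UWOPS culture left out. Strain was confounded with hours in meiosis (4 and 6), MNase units (20 and 40 against 10) and each strain's match to the reference. The count was 749 without YPS128 culture A (131 higher and 618 lower in UWOPS), 2354 without YPS128 culture B (2034 higher and 320 lower, the opposite balance), 35 without UWOPS culture A and 32 without its culture B, and quantile normalization gave 73 higher and 116 lower regions.

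Segments of at least 500 bp without any coverage were listed as a measure of sequence that gave no reads. Of 181 such segments in UWOPS (593 kb), 26 (55.4 kb) were covered in YPS128. One of them, VIII 7527 to 10524, spanned the whole of ARN2, a siderophore transporter gene, and 1.75% of COS8, and a shorter one picked for its gene, VIII 10676 to 12092, held 46.8% of PAU13, a seripauperin gene. Occupancy there in YPS128 was 1.11 and 0.664. The other long segments were XV 3159 to 11304, XVI 936727 to 942351, I 2697 to 8247, X 197915 to 202639, IX 207231 to 210643, I 8378 to 11777 and VII 707201 to 710533. In YPS128, 1 of 178 segments (506 kb) was covered in UWOPS, XIII 480726 to 481283. S. paradoxus had 341 segments (822 kb), S. mikatae 21 (25.4 kb) and S. kudriavzevii 1 (1.61 kb). These species were read in the coordinates of their own files, whose genomes are not named. Their counts therefore cannot be compared between species as missing sequence.

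The strains were next compared in the general form of their nucleosome landscapes. Neighbouring nucleosome peaks lay at a median distance of 168.5 ± 0.707 bp in YPS128, 167 ± 0 in UWOPS, 167.5 ± 0.707 in S. paradoxus, 169 ± 1.41 in S. mikatae and 168 ± 0 in S. kudriavzevii (SD, n = 2 each; exact permutation test, p = 0.302). NDR number per 100 kb was 66.2 ± 21.7, 59.4 ± 5.47, 51.1 ± 1.99, 59.7 ± 13.7 and 62.2 ± 5.17 in the same order (SD, n = 2 each). The median NDR width was 162.5 ± 21.9, 157.5 ± 3.54, 146 ± 1.41, 158 ± 14.1 and 154.5 ± 3.54 bp, and NDRs took up 9.07% to 13.9% of the covered genome. The contrast of the profile, its SD along the genome, was 0.620 ± 0.126, 0.629 ± 0.0253, 0.576 ± 0.0278, 0.60 ± 0.0686 and 0.579 ± 0.0252. No strain difference was shown in these measures (exact permutation tests of F over 945 partitions, 2-sided by construction). Hours in meiosis and MNase units also differed between strains, and S. mikatae cultures A and B were digested with 5 and 10 units. These tests therefore do not separate strain from digestion or time, and the S. mikatae SD includes a difference in units. The exact permutation p was 0.782 for number, 0.726 for width and 0.908 for contrast, all 0.908 when adjusted over 4 measures. For peak distance F was 2.08, so strains varied more than cultures of a strain, but the test was not passed. For number, width and contrast F was 0.425, 0.531 and 0.247. In these the YPS128 cultures had the largest SD, so smaller strain differences could have been missed. The spacing measure chosen before the data were examined, the lag of the highest autocorrelation between 130 and 210 bp, gave an exact permutation p of 0.213 (adjusted 0.851) but stood at the edge of its range, 130 bp, in 4 of the 10 cultures, so the peak distance is given first. The smallest p this design allows is 0.00106.

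**Figure D2:**
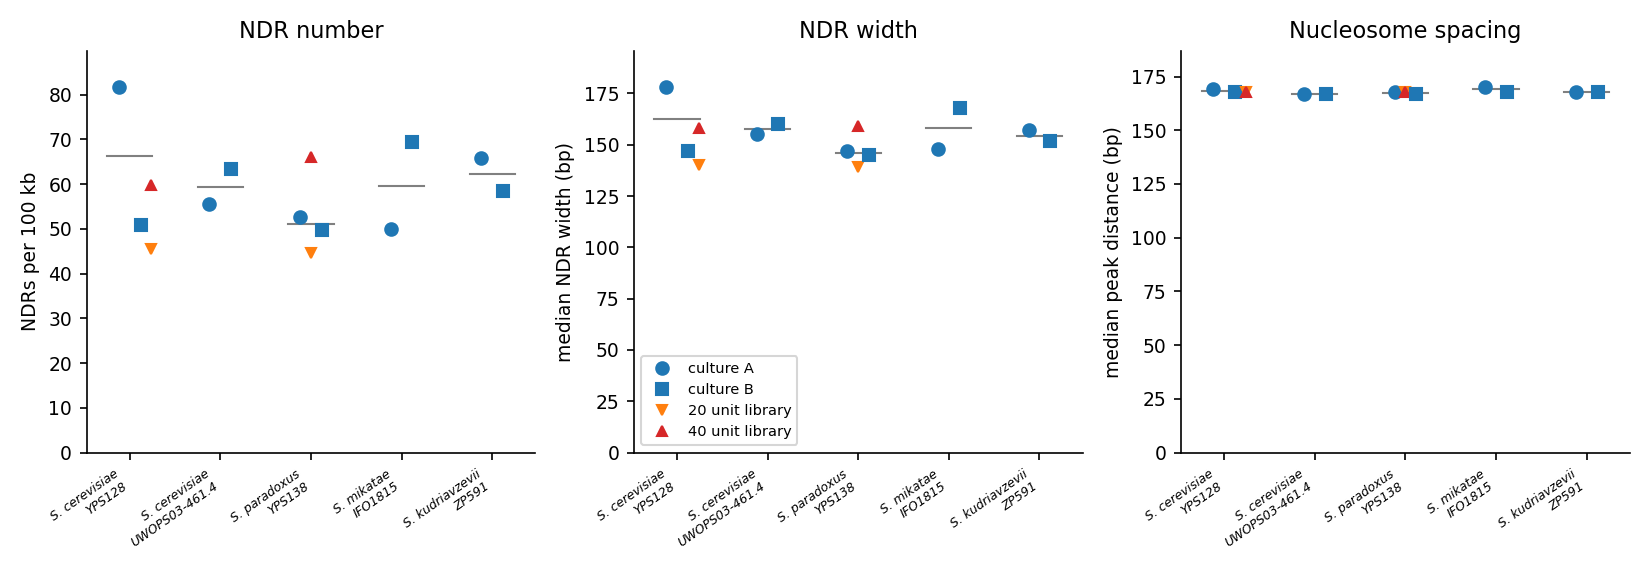
NDRs per 100 kb, median NDR width in bp and median distance between neighbouring nucleosome peaks in bp (y axes) for the 5 strains (x axis); circles and squares are cultures A and B, grey lines the strain means, and triangles the 20 and 40 unit libraries of the cultures digested with both. Cultures of YPS128 differ as widely (81.6 and 50.9 NDRs per 100 kb) as the strains do, while peak distances stay within 167 to 170 bp.

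Libraries of the same culture made with 20 and 40 units were set side by side, 1 library per amount, so that digestion was not separated from library preparation. In YPS128 culture B, 28 of the 102 gaps between convergent genes, where transcripts end, on chromosomes VIII and XIV (27.5%) held an NDR at 20 units and 71 (69.6%) at 40 units. Between divergent genes, whose promoters share the gap, the counts were 113 and 117 of 130 (86.9% and 90%), and in tandem gaps 248 and 270 of 293 (84.6% and 92.2%). Most divergent and tandem gaps held an NDR already at 20 units and had little room to rise, so their changes cannot be set against that of convergent gaps. Divergent gaps held an NDR in 89.2% to 90% of cases in the 4 S. cerevisiae cultures, and convergent gaps in 42.2% (YPS128 B), 57.8% and 74.5% (UWOPS A and B) and 88.2% (YPS128 A). These gap counts were chosen after the data had been examined and were not tested.

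Genome-wide, NDRs of YPS128 culture B rose in number from 5230 to 6879 (ratio 1.32), in median width from 140 to 158 bp, and the contrast went from 0.475 to 0.604. In S. paradoxus culture A the number went from 4988 to 7381 (ratio 1.48), the width from 139 to 159 bp and the contrast from 0.512 to 0.699. The peak distance was 168 bp in all 4 libraries. The 20 and 40 unit libraries correlated over 10 bp bins at r = 0.926 in YPS128 and 0.890 in S. paradoxus, and the 20 unit libraries of separate cultures at 0.880 and 0.937. Each pair is 1 culture, so there is no replicate check, and the libraries of YPS128 cultures A and B at 20 units differed 1.80 times in NDR number.

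The last comparison asked how much of the nucleosome profile is shared between species. Each 3 kb window of the YPS128 profile (3773 windows) was searched for in the whole profile of each other strain and counted as placed when a neighbouring window fell beside it in order. The share placed was 97.7% ± 0.206 in UWOPS, 59.8% ± 2.94 in S. paradoxus, 31.2% ± 2.66 in S. mikatae and 23.2% ± 0.337 in S. kudriavzevii (SD, n = 2 each). The shares differed between the 4 strains (exact permutation test, p = 0.00952, the smallest that 105 partitions allow), in a test added after the data had been examined. Among the 3 species alone 15 partitions allow no p below 0.0667, which was the exact permutation p reached. The median correlation of placed windows was 0.955, 0.839, 0.814 and 0.802. Each correlation is the best over a whole genome, so it can be high without a true match. In the reverse search, where few windows were placed, the median best correlation of all windows was 0.742 to 0.748 per culture. With the same search, windows of culture A were placed in culture B of their own strain in 99.5% to 100% of cases. No sequence was used, so these are similarities of profile. The shares depended on window size: 27.9%, 8.97% and 5.52% for the 3 species with 2 kb windows, and 78.5%, 65.9% and 59.7% with 5 kb windows.

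**Figure D3:**
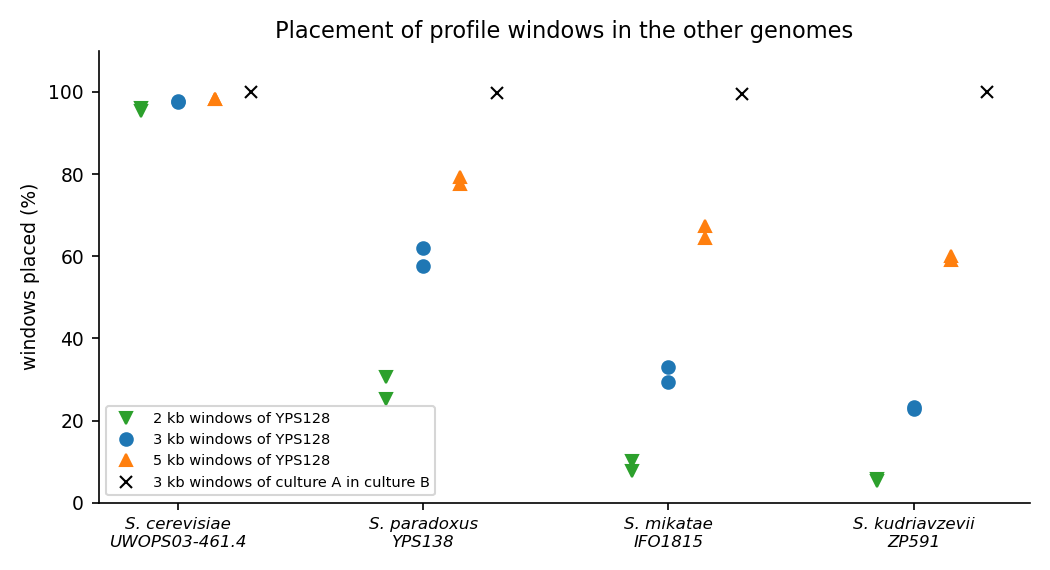
Percent of YPS128 windows placed (y axis) in each other strain (x axis), 1 point per culture, for windows of 2, 3 and 5 kb; crosses show 3 kb windows of culture A placed in culture B of the same strain. For 3 kb windows the share falls from 97.7% in UWOPS to 23.2% in S. kudriavzevii, while the crosses stay at or above 99.5%.

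The regions matched in every species included named genes on chromosomes VIII and XIV. In both cultures of all 3 other species 289 windows were placed, and 29 of them lay on these chromosomes. Independent placement would give 77.9, and 1000 shuffles gave at most 103. The shuffles moved single windows, whereas a window is placed only with a neighbour, and placement rose with the contrast of the YPS128 profile in every species. The excess therefore does not show that these regions were kept more than others. The highest mean correlations were 0.895 around the start of OCA5 (VIII 45001 to 48000), 0.891 around SLZ1 and YNL195C (XIV 270001 to 273000), 0.887 around RPL8A, a ribosomal protein gene, and GUT1, the glycerol kinase gene (VIII 36001 to 39000), 0.881 around SBP1 (VIII 33001 to 36000) and 0.880 around ACC1, the acetyl-CoA carboxylase gene, and TIM23, of the mitochondrial import channel (XIV 660001 to 663000). Windows near chromosome ends were placed less often. Within 30 kb of an end, 17.5% were placed in both S. paradoxus cultures, against 56.2% elsewhere, 6.28% against 24.3% in S. mikatae and 4.48% against 17.2% in S. kudriavzevii. By contrast of the YPS128 profile, the share rose from 34.7% in the 944 windows of lowest contrast to 65.6% in the 943 of highest contrast in S. paradoxus, from 9.53% to 38.1% in S. mikatae and from 5.72% to 27.1% in S. kudriavzevii. These windows and splits were chosen after the data had been examined and not tested further.

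Of the windows placed in forward orientation, 99.8% in S. paradoxus, 96.8% in S. mikatae and 99.9% in S. kudriavzevii lay on the chromosome of the same number. Few were placed in reverse, 60 and 73 windows in S. mikatae cultures A and B, of which 6.67% and 5.48% lay on the chromosome of the same number. In S. mikatae, 4 blocks lay elsewhere in both cultures. Windows from VI 162 to 255 kb of YPS128 matched VII 523.6 to 615.8 kb of S. mikatae, and windows from VII 555 to 870 kb matched VI 190.9 to 479.0 kb. Windows from VII 882 to 1053 kb matched XVI 44.5 to 214.4 kb, and windows from XVI 27 to 330 kb matched VI 494.3 to 794.2 kb, both in reverse orientation. These blocks held 12, 18, 17 and 35 windows in culture A and 12, 29, 24 and 35 in culture B. In S. paradoxus a block on IV 1167 to 1242 kb matched IV 970.0 to 1039.4 kb in reverse (17 and 11 windows), and 3 windows on XV 558 to 567 kb matched IV 1222.5 to 1231.4 kb. The largest block in both cultures in 100 shuffles held 2 windows. The shuffles moved windows separately in each culture, whereas cultures of a strain have like profiles and can share a false match. This comparison therefore cannot separate the 3 windows on XV from a false match. Blocks of at least 3 windows were sought after the data had been examined, and positions in the other species are in the coordinates of their own files.

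**Figure D4:**
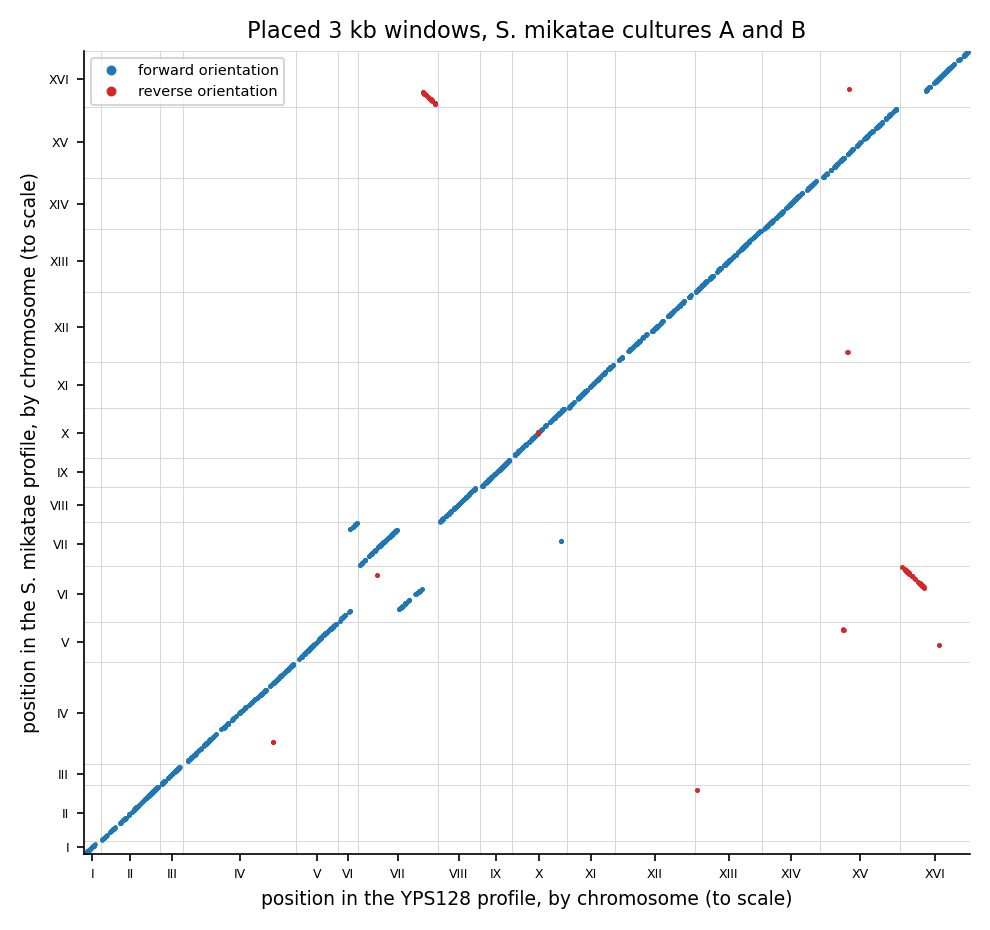
Position of each placed 3 kb window in the YPS128 profile (x axis) against its position in the S. mikatae profile (y axis), chromosomes I to XVI to scale, points of both cultures; blue is forward and red reverse orientation. Most points follow the diagonal, and 4 blocks connecting chromosomes VI, VII and XVI lie off it.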

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

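Of these settings, the crossed block and the shifts of the upstream window were chosen after the data had been examined. The count of 62 differing NDRs became 189 with quantile normalization, 30 and 182 with YPS128 culture B from its 20 or 40 unit library alone, and 188 without the coverage filter. It ranged from 32 (without UWOPS culture B) to 2354 (without YPS128 culture B) when 1 culture was left out, where the lone culture is assumed to vary like the others. The median log2 difference over all NDRs was 0.03, and became 0.28 without YPS128 culture B, -0.25 without its culture A and 0.15 with the 40 unit library alone. All 62 remained with quantile normalization and with the 40 unit library alone. That library correlated with YPS128 culture A at r = 0.951, against 0.880 for the 20 unit library. With a YPS128 culture left out, the variance came from the UWOPS cultures alone, which correlated at r = 0.965. Calls kept in such fits were therefore not a check of the 62. The 22.6% of calls that were higher in UWOPS became 38.6% with quantile normalization, 42.3% with the 40 unit library alone and 86.4% without YPS128 culture B. Pseudocounts, thresholds of 0.3 and 0.5 and a minimum width of 120 bp gave 46 to 85.

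The 3 genes, all higher in UWOPS, became 8 with quantile normalization (4 higher, 4 lower), 5 with the 40 unit library alone (4 and 1), 10 without the coverage filter (4 and 6) and 1, SNO2, with the lowest 50 bp upstream. Leaving out 1 culture gave 2 to 139, with 11 higher and 21 lower without YPS128 culture A and 122 and 17 without its culture B. The cause of these changes, and of those in the NDR count, was not tested. With culture letter as a replicate block, 56 NDRs passed (49 of the 62) and 5 genes; the letters are only names, and deviations of same-lettered cultures correlated at -0.494 over NDRs and -0.499 over genes. The crossed pairing gave 133 NDRs and 18 genes (8 higher, 10 lower). The block changed no gene group call. Of the log2 differences of the 31 named NDRs and genes, none changed sign in the settings it was run under (1 at each other occupancy threshold, 18 at the larger minimum width, 30 without the coverage filter, 3 for the window changes, 31 otherwise). Of them 10 did not pass with the 20 unit library alone, 13 without UWOPS culture A, 14 without culture B and 7 with the replicate block. Of the 58 strain values of named group members, the window from 200 to 1 bp moved 39 by more than their SD, the lowest 50 bp 52, the shifts 23 and 27, and either MNase amount alone 5.

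The share of windows placed moved with window size, to 95.7% (2 kb) and 98.2% (5 kb) in UWOPS, 27.9% and 78.5% in S. paradoxus, 8.97% and 65.9% in S. mikatae and 5.52% and 59.7% in S. kudriavzevii, with the order of strains kept. Segments covered in the other S. cerevisiae strain numbered 3 in YPS128 with occupancy under 0.02, and 14 in UWOPS at 1000 bp or more, and S. mikatae segments 12 at 1000 bp or more. NDR number, width, contrast and spacing stayed short of the threshold in every setting run, and the ratios of NDR number at 40 over 20 units were 1.28 and 1.49 at a threshold of 0.3. The S. cerevisiae comparison rests on 2 cultures per strain. At that number the simulated recovery of log2 1 changes in NDRs was 24.0%, without shifts of a whole culture.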

Other observations

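The tests of repeated sequence, of digestion over all NDRs, of NDR number and of the placed windows were chosen after their results had been seen, and the gene extremes were picked by their values. Upstream occupancy was lowest, averaged over 4 cultures, at ARE2, a sterol acyltransferase gene, at 0.0527 ± 0.0108, RPL14B at 0.0597 ± 0.00768, CRP1 at 0.0617 ± 0.0256, CPR8, a prolyl isomerase gene, at 0.0620 ± 0.0166, and TPM1, the tropomyosin gene, at 0.0636 ± 0.00865 (SD, n = 4 each). It was high in both strains at BIO5, a transporter gene of the biotin pathway, at 2.18 ± 0.252 and YHR130C at 2.48 ± 0.484 (SD, n = 4 each). Also high in both were YHL005C at 1.70 ± 0.124, MTC6 at 1.58 ± 0.172 and MID1, of a calcium channel, at 1.56 ± 0.144 (SD, n = 4 each).

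Gaps between divergent genes had a higher mean occupancy than those between convergent genes, 0.700 ± 0.0154 and 0.474 ± 0.138 in YPS128 and 0.709 ± 0.00173 and 0.482 ± 0.0274 in UWOPS (SD, n = 2 each). Divergent gaps were also longer, with a median of 421 bp against 271.5 bp. Tandem gaps had 0.527 ± 0.0715 and 0.524 ± 0.00923 (SD, n = 2 each).

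NDRs that differed between the S. cerevisiae strains were concentrated near chromosome ends, and on chromosomes VIII and XIV 8 of 11 lay inside genes such as FLO5, DOG1 and HXT17, a share not shown to exceed that of other regions depleted in 1 strain only (Fisher's exact test, p = 0.0880). The 20 and 40 unit libraries of YPS128 culture B differed by a median absolute log2 of 0.21 in these regions. The regions were selected for a large strain difference (median 2.28) and called on the mean of these libraries. Over all 7316 NDRs the libraries differed by 0.43 (0.16 between strains), at most 1.28 in any. The change from 20 to 40 units in YPS128 thus stayed below 2.28 in every region. That value is the median of regions selected for a large strain difference, so it is no bound for each of them. Over all NDRs the median change between units was larger than that between strains. Other differences in digestion stay open, since UWOPS was digested with 10 units only. The YPS128 cultures at 20 units also differed 1.80 times in NDR number. Repeated sequence piled on 1 copy stays open, since 12.9% (8 of 62) exceeded an occupancy of 2 in the higher strain. These included 6 of the 10 largest falls, and the handling of reads with several matches is not given in the sources used here. CUP1-1 and CUP1-2 had no coverage in either strain. Reads of repeated sequence may therefore also have been lost, which was not tested. Sequence of UWOPS that does not align stays open too: bases covered only in YPS128 flanked 8 of the 48 lower regions (16.7%, exact 95% interval 7.48% to 30.2%), 3.06 times the share of other NDRs at like distance from an end, and in the mirror case bases covered only in UWOPS flanked 2 of the 14 higher regions (14.3%, 1.78% to 42.8%; 11.7 times). A difference of the strains in sequence or in nucleosome placement remains a hypothesis, and hours in meiosis cannot be told apart from strain.

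The spread of NDR number between cultures of a strain, 81.6 and 50.9 per 100 kb in YPS128, may come from the extent of digestion. The number was 1.32 and 1.48 times higher at 40 than at 20 units in YPS128 and S. paradoxus (1.28 and 1.49 times at a threshold of 0.3), with 1 library per amount, so library preparation was not separated. Depth is argued against, since the YPS128 libraries at 20 units had mean coverage 1.01 times apart (medians of 119 in A and 133 in B) and NDR numbers 1.80 times apart. As those libraries had the same nominal units, units alone do not set the number, and a difference between the cultures themselves was not tested.

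The share of placed windows fell from S. paradoxus to S. kudriavzevii by 36.6 percentage points. Noise of lower coverage is argued against, because single S. paradoxus libraries with mean coverage of 58.3, 67.1 and 73.5 had 56.9%, 50.2% and 57.7% of windows placed, and S. kudriavzevii libraries with 58.3 and 67.0 had 22.9% and 23.4%, at least 26.8 points less. The 40 and 20 unit libraries of S. paradoxus culture A differed by 6.76 points, well under the fall. Loss of profile similarity with species distance is a hypothesis that these tests leave standing; changes of spacing between genes and of nucleosome placement within them were not separated, and hours in meiosis and, for S. mikatae, media differed too.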
